A study of Homo sapiens with 9 samples.

How the data were processed

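RNA was taken from MOLM13 cells after 72 h with DMSO, 1 µM iberdomide or 50 nM mezigdomide, 3 libraries per group. Per the labels' protocols, poly(A) RNA was selected, libraries were prepared with a NEBNext Ultra RNA kit, which is not stated to keep strand, and read as 37 bp paired-end reads on an Illumina NextSeq. The submitters' processing notes name bcl2fastq 2.20.0.422, STAR 2.7.5a, Picard 2.9.4, SAMtools 1.95, HTSeq 0.6.1pl and DESeq2, with the human build GRCh38 (hg38). They give no role or order for these tools. The annotation release and the counting options are not given in the sources used here. The names of the deposited results hold the label rmdup, but whether duplicate reads or duplicate rows were removed is not stated.

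The authors deposited 2 tables of 59699 rows, each comparing a drug with DMSO, and no column of per-sample values was used here. Per the file headers, each row holds what DESeq2 reports: a mean normalised count, a log2 fold change of treated over DMSO, its standard error, a Wald statistic, a p-value and an adjusted p-value. The deposited mean signal is the mean over all libraries of counts divided by size factors, and it is identical in both tables, so that both comparisons came from a fit over all 9 libraries. The deposited score, the Wald statistic, equals the log2 fold change over its standard error within 1.56e-13. The deposited p-value is the two-sided normal p of that statistic, and the adjusted p-value is its Benjamini-Hochberg value over the genes above a mean of 2.87 (iberdomide) or 2.01 (mezigdomide), recomputed here within 2e-15. The deposited log2 fold changes are shrunk towards 0, since genes with 1 read in all 9 libraries have absolute values of at most 0.0132, so that the changes of low genes are understated.

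Library depth was recovered from the mean. The mean of a gene with 1 read in 1 library depends only on that library's size factor. The 9 commonest mean values, held by 4741 genes, were taken as those of such genes, 1 value for each library. The number of values was set to the number of libraries, so it is no check of the method. The size factors were 0.889 to 1.08, and with a summed mean of about 23500000 normalised counts the depths were about 20900000 to 25300000 counted reads. These depths are approximate, and they were not tied to groups or replicates.

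The design written beforehand took a count test over the libraries as the main test. The tables hold no counts, so the authors' own Wald test is reported in its place. A replicate block, leaving out each replicate, other normalizations, another test, a fit of the 6 libraries of a contrast, an estimated correlation between genes, a self-contained list test, other pseudocounts and other splits of the libraries could not be computed for the same reason. From the tables, 44 rows for second copies on chromosome Y of genes shared with chromosome X (highest mean 92.1) and 92 rows that name no gene, with 3.39e-05% of the normalised counts, were left out. This left 19497 genes tested under both drugs and 20819 tested under mezigdomide, and removed no called gene. Genes were called at an adjusted p under 0.05, and an adjusted p missing from a table was left missing.

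The difference between the drugs was computed as the mezigdomide minus the iberdomide log2 fold change. Its standard error took both errors as independent, which is an upper limit because the shared DMSO libraries make them correlate positively. A two-sided normal test with Benjamini-Hochberg adjustment over 19497 genes was applied, and 95% intervals were taken from the same error. The spread of the difference statistic over genes was 0.653 as a robust SD, where 0.707 is the value with no effect at an error correlation of 0.5, so a test at that correlation was added as an alternative. Data were simulated for this comparison (19497 genes), with changes planted only in genes with a mean of at least 100 normalised counts and not shrunk. How often changes in lower genes or shrunken changes are found was therefore not measured. On these data the test with independent errors called 22 of 50 genes changed 1.5-fold, 49 of 50 changed 2-fold, all 50 changed 3-fold, all 50 changed 4-fold and 0 of 19297 unchanged genes. With an error correlation of 0.5 it called 43, 50, 50 and 50, and 5 unchanged genes.

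The 19 gene lists were fixed before the data were examined and tested with limma's cameraPR on the Wald or difference statistic, with a preset correlation between genes of 0.01, two-sided, and Benjamini-Hochberg adjustment over 57 tests. This test took the genes tested under both drugs, while counts and medians under mezigdomide took every member tested there. Under mezigdomide it thus covered 9 of 11 stem and progenitor, 34 of 35 interferon, 20 of 21 surface antigen and 8 of 10 lymphoid members. In the simulated data 1 of 19 lists was called, the 1 that had been shifted. Those statistics were drawn with no correlation between genes and adjusted over 19 tests. They therefore do not measure false calls where genes correlate. The genes named are those of a rule set beforehand. It takes the 10 largest rises and 10 largest falls among called genes with a mean of at least 100 normalised counts, up to 4 members per list with the smallest p, and IKZF1, IKZF3, CRBN, GSPT1, MEIS1, HOXA9, FLT3, MYC, CD86, ITGAM and BCL2 whatever their p. Not every gene that it takes is named in the text. Its condition that replicates of the groups do not overlap could not be applied. Members named as the other called genes of a small count were chosen after their values were seen. Of the tested genes 98.5% had a GC content and length, taken from the longest transcript in GENCODE release 29 on GRCh38, which also gave the coordinates and exon overlaps. The trend with both was removed by lowess with a span of 0.3. The overlap expected from shared controls came from 100 simulations of unchanged groups.

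Alternatives set beforehand that could be run were no filter on low counts, a mean of at least 50 normalised counts and an absolute log2 fold change of at least 1. Centring of the fold changes, removal of the GC and length trend, protein-coding genes only, the error correlation of 0.5, preset correlations of 0.05 and 0.1 and a rank-based list test were added after seeing the data. Further lists for the closing observations were also chosen after seeing the data. Computations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.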

Results

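Poly(A)-selected RNA was sequenced from MOLM13, an established human acute myeloid leukaemia (AML) cell line that carries a KMT2A rearrangement and an activating FLT3 duplication. Cells were exposed for 72 h to the solvent DMSO, to 1 µM iberdomide (CC-220) or to 50 nM mezigdomide (CC-92480), with 3 libraries in each of the 3 groups and 9 in all. Both drugs bind cereblon, the substrate receptor of an E3 ubiquitin ligase, and direct it to the lymphoid transcription factors IKZF1 and IKZF3. The values analysed here are the log2 fold changes over DMSO, standard errors (SE) and adjusted p-values of 2 tables of comparisons deposited by the authors, which hold no value per library. The replicate spread therefore enters only through the SE. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so that the p-values measure the spread between these libraries, which may be technical. The depth of the 9 libraries, recovered from genes taken to have 1 read in 1 library, ran from about 20900000 to 25300000 counted reads.

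The first comparison asked which transcripts differed after iberdomide. SPARC, a secreted matrix glycoprotein (chromosome 5, 151661096 to 151687165, GRCh38), stood 137-fold above DMSO in the authors' deposited table, a log2 fold change of 7.10 with an SE of 0.14. TREM2, a lipid-sensing receptor of macrophages (chromosome 6, 41158506 to 41163186), rose 19.9-fold (log2 4.31, SE 0.092), and SIGLEC1, the macrophage sialoadhesin, rose 14.7-fold (log2 3.87, SE 0.17) in the authors' deposited table. In the opposite direction, IGLL1, a surrogate light chain gene (chromosome 22, 23573125 to 23580308), fell to 0.0857 of its DMSO level in the authors' deposited table, a log2 fold change of -3.55 with an SE of 0.16.

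Among the other genes with the largest rises, the authors' deposited table gives log2 fold changes of 4.03 for the interleukin receptor gene IL17RE, 3.82 for the calprotectin subunit S100A9, 3.79 for the serpin SERPINB2 and 3.64 for complement C3. SIGLEC11 and ACE, the angiotensin-converting enzyme, follow in the authors' deposited table at 3.53 and 3.46. ABCA1, the membrane exporter of cholesterol to apolipoproteins (chromosome 9, 104781002 to 104928237), rose 11.3-fold, with a log2 fold change of 3.50 and an SE of 0.18 in the authors' deposited table. The remaining large falls in the authors' deposited table were in KLC2 (-2.64), C11orf95 (-2.57), LRFN3 (-2.52), the angiopoietin ANGPT1 (-2.35), the elongation factor EEF1A2 (-2.14), the cytokine receptor chain IL2RG (-2.04), CERCAM (-1.92), FOXA1 (-1.89) and the retinaldehyde dehydrogenase ALDH1A3 (-1.89).

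**Figure D1:**
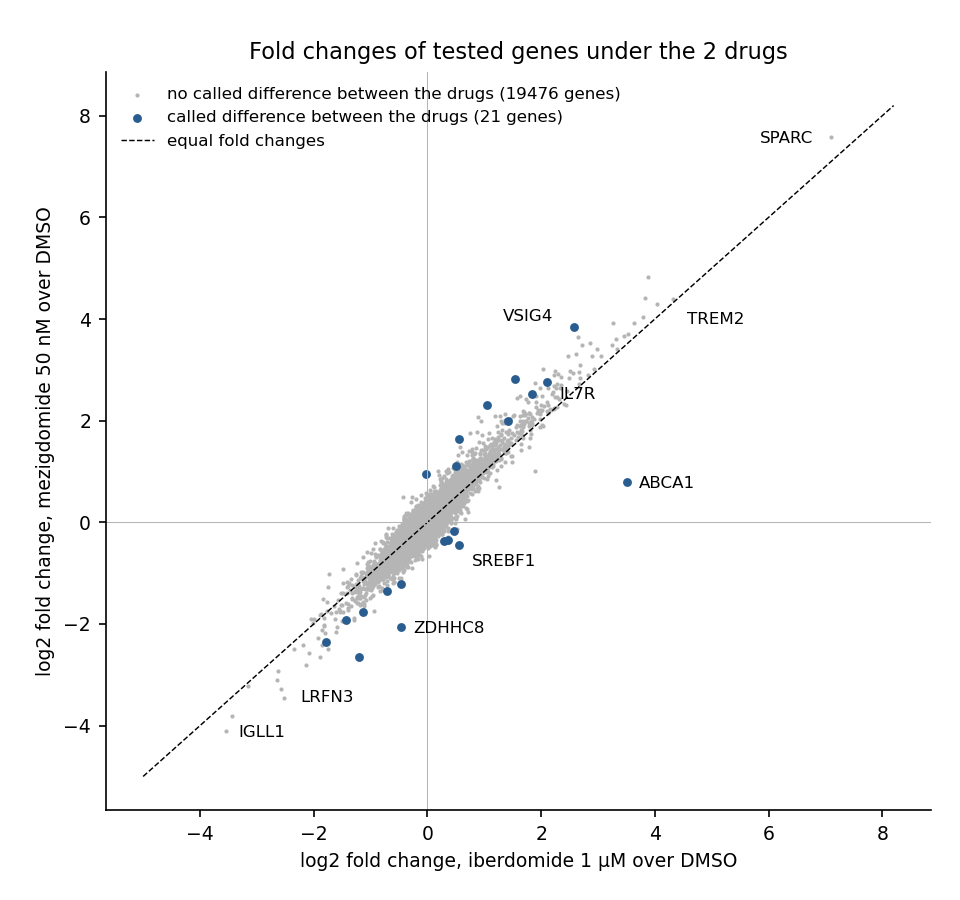
Log2 fold change over DMSO of each of 19497 tested genes, under iberdomide at 1 µM (horizontal axis) and mezigdomide at 50 nM (vertical axis), from the authors' deposited table of each drug. Blue points are the 21 genes with a called difference between the drugs, and the dashed line marks equal fold changes. SPARC lies at the far upper right at 7.10 and 7.58, while ABCA1 lies far below the line at 3.50 and 0.80.

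In all, 2743 of 19497 genes (14.1%) passed an adjusted p of 0.05 under iberdomide by the authors' deposited table, 1424 higher and 1319 lower than under DMSO. Of the 19 gene lists fixed before the data were examined, markers of monocyte and macrophage maturation had the smallest p in the camera test. Of their 24 measured members 15 rose and 2 fell by the authors' deposited table, and 17 and 3 did so adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.26e-40). In a rank-based test their adjusted p of 0.000102 came behind cholesterol synthesis (1.04e-09), integrated stress response (1.58e-08) and S phase genes (3.24e-05). Single members of the monocyte and macrophage list are given next. Examples in the authors' deposited table are the phagocyte oxidase subunit CYBB at 2.28 (SE 0.097), the scavenger receptor CD36 at 1.41 (SE 0.079) and the chemokine receptor CCR2 at 1.28 (SE 0.058). CD86 and ITGAM, which are often used as surface markers of this maturation, did not pass, at 0.31 (Wald test, Benjamini-Hochberg adjusted p = 0.187) and -0.32 (adjusted p = 0.176) in the authors' deposited table. MHC class II presentation genes had 7 of 13 members higher and 0 lower by the authors' deposited table, 9 and 0 adjusted over the list alone (camera adjusted p = 1.55e-09). The peptide-binding chain HLA-DRA stood at 1.84 (SE 0.11), the peptide-loading chain HLA-DMA at 1.72 (SE 0.14) and CIITA, the master regulator of the class, at 1.09 (SE 0.16) in the authors' deposited table. CD74, a member with a mean of 3647.37 normalised counts, did not pass the Wald test (-0.10, adjusted p = 0.331) in the authors' deposited table. Reads of the polymorphic HLA genes can be shared between near-identical copies, so that the values of HLA-DRB1 (1.32) and HLA-DQB1 (1.42) in the authors' deposited table are uncertain. MHC class I genes had 1 member higher, NLRC5, and 1 lower, ERAP2, of 15 by the authors' deposited table, with the same counts adjusted over the list alone (camera adjusted p = 0.921). The fall of ERAP2, -0.21 in the authors' deposited table, did not pass with no filter on low counts, which leaves its value as it is (adjusted p = 0.0764), or after centring of the fold changes (-0.20, adjusted p = 0.0573).

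Granule and neutrophil genes had 5 of 15 members higher and 2 lower under iberdomide by the authors' deposited table, and as many adjusted over the list alone (camera adjusted p = 4.69e-05, 0.207 in a rank-based test). The serpin SERPINB10 at 3.04 (SE 0.093) and myeloperoxidase MPO at 0.91 (SE 0.063) rose in the authors' deposited table, while CEBPE, a regulator of late granulocyte maturation, fell by 1.81 (SE 0.16). SERPINB10 shares 20.3% of its exon bases with SERPINB2 on the same strand, so that reads of this pair may not be separable. Stem and progenitor genes had 4 of 9 members lower and 0 higher by the authors' deposited table, 5 and 0 adjusted over the list alone (camera adjusted p = 5.16e-06). They were ANGPT1, named above, the progenitor regulators GATA2 (-1.19, SE 0.094) and SOX4 (-0.73, SE 0.094), and LYL1 (-0.45, SE 0.10) in the authors' deposited table.

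Genes of the integrated stress response, the amino acid and protein stress programme driven by ATF4, had 19 of 26 members lower and 0 higher under iberdomide by the authors' deposited table, and 19 and 0 adjusted over the list alone (camera adjusted p = 1.79e-12). The asparagine synthetase ASNS (-0.76, SE 0.084), the serine synthesis enzyme PHGDH (-0.57, SE 0.075), DDIT4 (-1.48, SE 0.21) and the secreted protein STC2 (-2.02, SE 0.22) had the smallest p among them in the authors' deposited table. Cholesterol synthesis genes had 20 of 23 members lower and 0 higher by the authors' deposited table, and 20 and 0 adjusted over the list alone (camera adjusted p = 1.2e-12). They included HMGCS1 (-0.92, SE 0.13), MVD (-0.74, SE 0.12) and CYP51A1 (-0.62, SE 0.093) in the authors' deposited table. S phase and DNA replication genes had 9 of 28 lower and 0 higher by the authors' deposited table, 10 and 0 adjusted over the list alone (camera adjusted p = 0.00104, 0.103 with a preset correlation of 0.1). The transcription factor E2F2 stood at -0.71 (SE 0.10) and the helicase subunit MCM5 at -0.21 (SE 0.056) in the authors' deposited table. G2 and mitosis genes had 4 of 28 lower, CDC20, HMMR, PLK1 and BUB1, and 0 higher by the authors' deposited table, with the same counts adjusted over the list alone (camera adjusted p = 0.00847, 0.075 with a preset correlation of 0.05 and 0.188 with 0.1).

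Early response genes of AP-1 and NF-kB had 3 members higher and 11 lower of 26 by the authors' deposited table, and as many adjusted over the list alone (camera adjusted p = 0.0319, 0.126 after removal of a trend with GC content and transcript length, 0.0553 with a mean of at least 50, 0.138 with a preset correlation of 0.05 and 0.285 with 0.1). The transcription factor FOS (0.89, SE 0.14) and the cytokine TNF (0.65, SE 0.10) were higher, and EGR3 (-1.35, SE 0.22) and JUND (-0.62, SE 0.12) lower, in the authors' deposited table. Type I interferon response genes had 9 of 34 higher and 2 lower by the authors' deposited table, 11 and 2 adjusted over the list alone (camera adjusted p = 0.0282, 0.233 in a rank-based test, 0.142 with a preset correlation of 0.05 and 0.3 with 0.1). OAS3 at 2.18 (SE 0.18), IFITM3 at 1.97 (SE 0.11) and STAT2 at 0.56 (SE 0.11) rose, while IRF1 fell by 0.64 (SE 0.12) in the authors' deposited table. Lymphoid markers had 1 of 8 higher and 1 lower by the authors' deposited table, with the same counts adjusted over the list alone. The camera test called them higher (adjusted p = 0.0373, 0.0832 with a preset correlation of 0.05 and 0.157 with 0.1) although their median was -0.0074, and a rank-based test gave the opposite direction (adjusted p = 0.853). The called members were the interleukin receptor IL7R at 2.10 (SE 0.090) and the T cell receptor chain CD3D at -0.85 (SE 0.23), the latter at a mean of 19.1 normalised counts in the authors' deposited table.

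Components and known substrates of the cereblon ligase had 4 of 20 members higher and 1 lower by the authors' deposited table, and as many adjusted over the list alone (camera adjusted p = 0.111). IKZF1 (chromosome 7, 50304068 to 50405101) rose 1.7-fold (log2 0.76, SE 0.11), IKZF2 stood at 1.49 (SE 0.17) and ZNF692 at 1.16 (SE 0.12), while ZBTB16 fell by 0.83 (SE 0.12) in the authors' deposited table. Transcripts of CRBN itself (0.028, adjusted p = 0.9) and of the translation termination factor GSPT1 (-0.071, adjusted p = 0.555) did not pass in the authors' deposited table. IKZF3 was near the detection limit, with a mean of 3.61 normalised counts in the authors' deposited table. Targets of KMT2A fusions and menin had 1 of 27 higher and 5 lower by the authors' deposited table, and as many adjusted over the list alone (camera adjusted p = 0.177). HOXA5 (-0.51, SE 0.092) and DOT1L (-0.43, SE 0.12) were among those that fell, and LMO2 (0.32, SE 0.081) rose, in the authors' deposited table. MEIS1 (-0.084, adjusted p = 0.7), HOXA9 (-0.083, adjusted p = 0.672), FLT3 (-0.028, adjusted p = 0.894) and BCL2 (0.16, adjusted p = 0.435) did not pass the Wald test in the authors' deposited table.

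AML surface antigens and immune ligands had 4 of 20 members higher and 5 lower by the authors' deposited table, 4 and 6 adjusted over the list alone (camera adjusted p = 0.184). LILRB4 (0.44) and CLEC12A (0.77) rose and the adhesion receptor CD44 (-1.06) and the homing receptor CXCR4 (-0.82) fell in the authors' deposited table. MYC and ribosome biogenesis genes had 1 of 25 higher, MYC at 0.19 (adjusted p = 0.0239), and 1 lower, PPAN, by the authors' deposited table, with the same counts adjusted over the list alone (camera adjusted p = 0.144, 0.0073 in a rank-based test). PPAN, at -0.23 in the authors' deposited table, lost its call after removal of a GC and length trend (-0.094, adjusted p = 0.53). BCL2 family genes had 2 of 17 higher, BCL2L2 and BCL2L11, and 0 lower by the authors' deposited table, 5 and 1 adjusted over the list alone (camera adjusted p = 0.564). BCL2L11, at 0.28 in the authors' deposited table, lost its call after removal of the GC and length trend with its fold change little moved (0.24, adjusted p = 0.0793). p53 targets had 4 of 24 higher and 2 lower, 5 and 3 adjusted over the list alone (camera adjusted p = 0.611), and erythroid and megakaryocyte markers 1 of 10 higher and 2 lower, as many adjusted over the list alone (camera adjusted p = 0.823), by the authors' deposited table. The test of these fold changes was the authors' Wald test with Benjamini-Hochberg adjustment. The list test took a preset correlation between genes of 0.01, since none could be estimated without values per library. The Wald statistic declined with GC content across 19210 genes (Spearman rho = -0.194) and was higher in longer transcripts (rho = 0.128). In genes with a mean of at least 100 normalised counts these values were -0.231 and 0.248. The fifth of genes richest in GC had a median log2 fold change of -0.091. Values here and below are uncertain for genes that share at least 10% of their exon bases with another annotated gene, since their reads may not be separable. On the same strand the shares were 79.4% in CYP51A1, 56.0% in PPAN, 50.8% in IL2RG, 44.6% in ASNS, 23.9% in ACE, 19.4% in BCL2L2, 13% in LILRB4, 13.1% in HOXA9 and 11.5% in CIITA. The kit is not stated to separate strands. On the opposite strand the shares were 41.2% in DDIT4, 27.5% in ALDH1A3, 22.0% in IRF1, 21.3% in IFITM3, 18.6% in FDPS, 15% in HMGCS1, 11.8% in RARA, 11.6% in PLK1 and in CIITA, and 10.9% in BCL2L11.

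**Figure D2:**
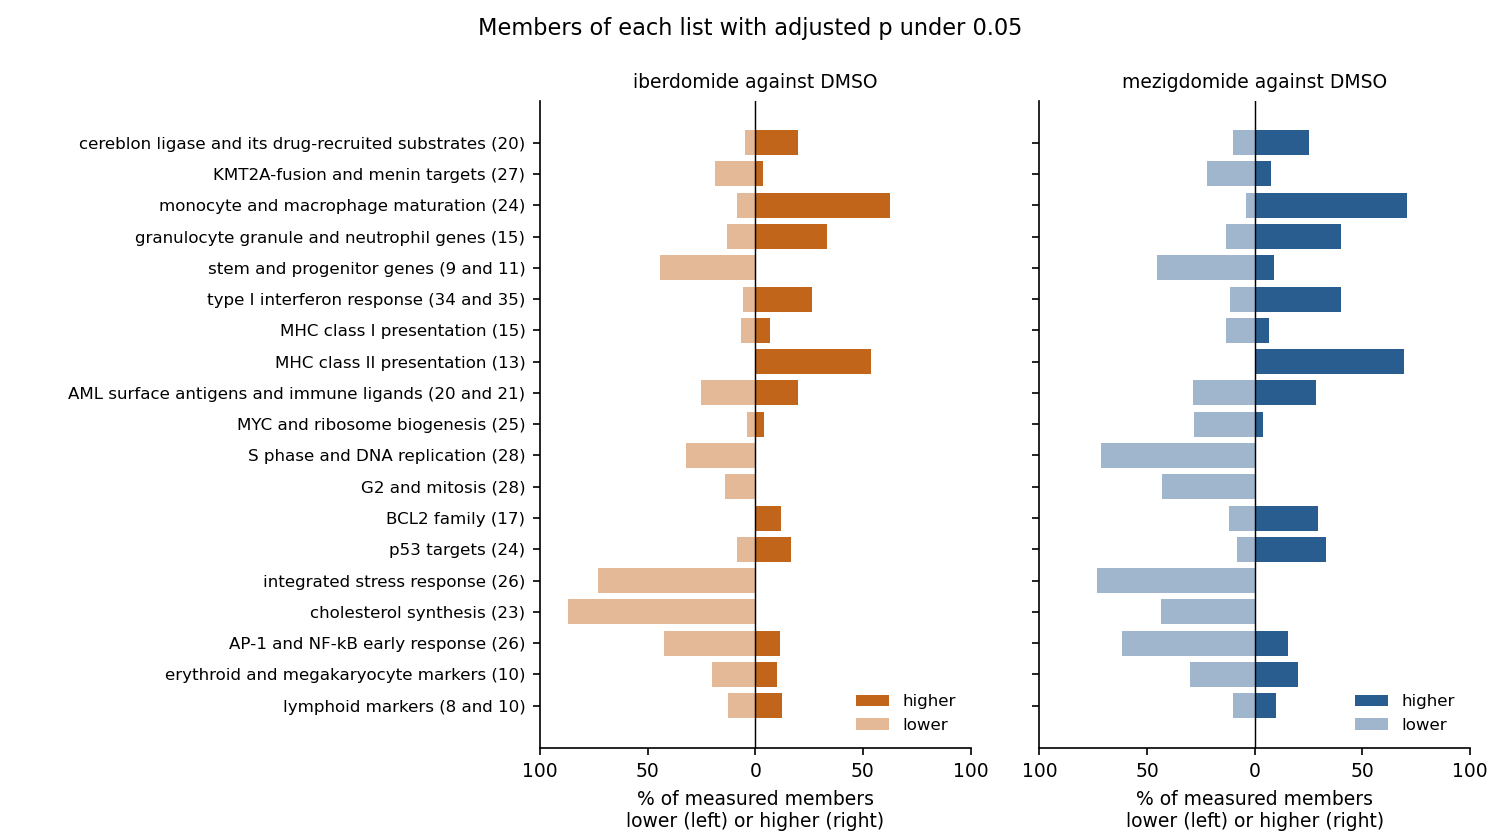
Share of the measured members of each of 19 gene lists that were higher (dark bars, right) or lower (light bars, left) than DMSO at an adjusted p under 0.05 in the authors' deposited table, under iberdomide (left panel) and mezigdomide (right panel). The number of measured members stands beside each name. Monocyte and macrophage genes had 15 of 24 members higher under iberdomide and 17 under mezigdomide, and cholesterol synthesis genes 20 and 10 of 23 lower.

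The second comparison asked the same of mezigdomide. SPARC rose 191-fold (log2 7.58, SE 0.14), SIGLEC1 28.2-fold (log2 4.82, SE 0.17), S100A9 21.2-fold (log2 4.41, SE 0.12) and TREM2 20.9-fold (log2 4.39, SE 0.092) in the authors' deposited table. Next by size in the authors' deposited table came IL17RE (4.29), SERPINB2 (4.04), the lectin CD209 (3.93), C3 (3.91), VSIG4, a complement receptor of tissue macrophages (3.84), and SIGLEC11 (3.70). The largest falls in the authors' deposited table were in IGLL1 (-4.10, SE 0.17), LRFN3 (-3.46, SE 0.18), C11orf95 (-3.28, SE 0.18) and KLC2 (-3.10, SE 0.16). EEF1A2 (-2.82), FOXA1 (-2.64), ANGPT1 (-2.50), SIDT2 (-2.49), the eosinophil peroxidase EPX (-2.36) and CERCAM (-2.27) completed that group in the authors' deposited table.

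Under mezigdomide 4405 of 20819 genes (21.2%) passed by the authors' deposited table, 2172 higher and 2233 lower. Monocyte and macrophage genes had 17 of 24 members higher and 1 lower by the authors' deposited table, 18 and 2 adjusted over the list alone (camera adjusted p = 3.26e-40). CYBB stood at 2.27 (SE 0.097), S100A8 at 2.86 (SE 0.18), CCR2 at 1.53 (SE 0.058) and CD86 at 0.43 (adjusted p = 0.0248) in the authors' deposited table, while ITGAM did not pass (0.045, adjusted p = 0.896). MHC class II genes had 9 of 13 members higher and 0 lower by the authors' deposited table, 11 and 0 adjusted over the list alone (camera adjusted p = 8.18e-15). HLA-DRA reached 2.53 (SE 0.11), HLA-DMA 2.12 (SE 0.14) and CIITA 1.76 (SE 0.16) in the authors' deposited table. CD74 did not pass the Wald test here either (0.14, adjusted p = 0.0915). MHC class I genes had 1 of 15 higher, NLRC5, and 2 lower, TAP1 and PSMB9, by the authors' deposited table, as many adjusted over the list alone (camera adjusted p = 0.862). Both lost their calls with the GC and length trend removed. TAP1 stood at -0.26 (SE 0.079, adjusted p = 0.00719) in the authors' deposited table and at -0.17 (adjusted p = 0.114) after removal. PSMB9 stood at -0.38 (SE 0.15, adjusted p = 0.0468) in the authors' deposited table and, little moved, at -0.37 (adjusted p = 0.0591) after removal. ERAP2 did not pass in the authors' deposited table (-0.19, adjusted p = 0.0608) and passed after removal (-0.30, adjusted p = 0.00129). It also passed with a mean of at least 50 (adjusted p = 0.0425) and with protein-coding genes only (adjusted p = 0.0428). Granule and neutrophil genes had 6 of 15 higher and 2 lower by the authors' deposited table, 7 and 4 adjusted over the list alone (camera adjusted p = 3.07e-05, 0.225 in a rank-based test). SERPINB10 (3.27), MPO (1.11) and MS4A3 (1.02) rose and CEBPE (-1.88) and AZU1 (-0.31) fell in the authors' deposited table. Stem and progenitor genes had 5 of 11 lower and 1 higher by the authors' deposited table, 6 and 2 adjusted over the list alone (camera adjusted p = 3.07e-05, 0.06 in a rank-based test). GATA2 (-1.48, SE 0.095) and SOX4 (-0.88, SE 0.094) fell, and the growth factor receptor KIT (0.97, SE 0.23) rose from a mean of 15.6 normalised counts, in the authors' deposited table.

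S phase genes had 20 of 28 members lower and 0 higher under mezigdomide by the authors' deposited table, 21 and 0 adjusted over the list alone (camera adjusted p = 2.63e-08). E2F2 (-1.15, SE 0.10), the licensing factor CDT1 (-0.54, SE 0.085), CDC45 (-0.43, SE 0.071) and MCM5 (-0.34, SE 0.056) were among them in the authors' deposited table. G2 and mitosis genes had 12 of 28 lower and 0 higher by the authors' deposited table, 15 and 0 adjusted over the list alone (camera adjusted p = 0.00206, 0.131 with a preset correlation of 0.1), with PLK1 at -0.35 and CDC20 at -0.40. Integrated stress response genes had 19 of 26 lower and 0 higher by the authors' deposited table, 20 and 0 adjusted over the list alone (camera adjusted p = 2.38e-11). STC2 (-1.99, SE 0.22), TRIB3 (-0.90, SE 0.12), ASNS (-0.81, SE 0.084) and PHGDH (-0.73, SE 0.075) fell in the authors' deposited table. Cholesterol synthesis genes had 10 of 23 lower and 0 higher by the authors' deposited table, 16 and 0 adjusted over the list alone (camera adjusted p = 0.00157, 0.103 with a preset correlation of 0.1). INSIG1 (-0.70, SE 0.099), FDPS (-0.42, SE 0.091) and HMGCS1 (-0.41, SE 0.12) fell in the authors' deposited table.

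Early response genes of AP-1 and NF-kB had 4 of 26 higher and 16 lower by the authors' deposited table, 4 and 17 adjusted over the list alone (camera adjusted p = 0.00357, 0.146 with a preset correlation of 0.1). EGR3 (-1.65) and JUND (-0.73) fell and FOS (0.71) and FOSL2 (0.66) rose in the authors' deposited table. Type I interferon response genes had 14 of 35 higher and 4 lower by the authors' deposited table, as many adjusted over the list alone (camera adjusted p = 0.00357, 0.0582 with a preset correlation of 0.05 and 0.17 with 0.1). OAS3 stood at 2.53 (SE 0.18) and IFITM3 at 1.87 (SE 0.11) in the authors' deposited table. p53 targets had 8 of 24 higher and 2 lower by the authors' deposited table, 9 and 2 adjusted over the list alone (camera adjusted p = 0.0593). Among the members that rose in the authors' deposited table were RRM2B (0.55, SE 0.066), the p53 ubiquitin ligase MDM2 (0.48, SE 0.069) and ZMAT3 (0.62, SE 0.097). MYC and ribosome biogenesis genes had 1 of 25 higher, MYC at 0.23 (adjusted p = 0.00417), and 7 lower by the authors' deposited table, 1 and 8 adjusted over the list alone (camera adjusted p = 0.0541, 0.00268 in a rank-based test and 0.118 with the GC and length trend removed). Of the members lower, PPAN (-0.27) and BOP1 (-0.33) in the authors' deposited table lost their calls after that removal, at -0.053 (adjusted p = 0.705) and -0.093 (adjusted p = 0.617). BCL2 family genes had 5 of 17 higher and 2 lower by the authors' deposited table, 7 and 3 adjusted over the list alone (camera adjusted p = 0.675), with the pro-apoptotic BCL2L11 at 0.42 (SE 0.095), PMAIP1 at -0.40 (SE 0.13) and BCL2 itself not past the test (0.27, adjusted p = 0.0748).

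Cereblon ligase components and substrates had 5 of 20 higher and 2 lower under mezigdomide by the authors' deposited table, as many adjusted over the list alone (camera adjusted p = 0.127). IKZF1 rose 1.97-fold (log2 0.98, SE 0.11), and CRBN did not pass (-0.065, adjusted p = 0.647), in the authors' deposited table. GSPT1 did not pass in the authors' deposited table (-0.072, adjusted p = 0.467), but did after removal of the GC and length trend (-0.20, adjusted p = 0.00516). KMT2A-fusion and menin targets had 2 of 27 higher, JMJD1C and LMO2, and 6 lower by the authors' deposited table, as many adjusted over the list alone (camera adjusted p = 0.297). MEIS1 (-0.055, adjusted p = 0.771), HOXA9 (-0.15, adjusted p = 0.239) and FLT3 (0.085, adjusted p = 0.481) did not pass in the authors' deposited table, while HOXA5 fell by 0.65 (SE 0.092). HOXA9 shares 13.9% of its exon bases with the opposite-strand HOXA10-AS, and the library kit is not stated to keep strand. AML surface antigens had 6 of 21 higher and 6 lower, as many adjusted over the list alone (camera adjusted p = 0.431), and erythroid and megakaryocyte markers 2 of 10 higher and 3 lower, as many adjusted over the list alone (camera adjusted p = 0.637), by the authors' deposited table. CD38 (0.36) and the stress ligand MICA (0.50) rose and CD44 (-1.21) and CXCR4 (-0.87) fell in the authors' deposited table. Lymphoid markers had 1 of 10 higher, IL7R at 2.75 (SE 0.089), and 1 lower, CD3D, by the authors' deposited table, with the same counts adjusted over the list alone. Their median over these 10 was -0.15. The camera test took only the 8 tested under both drugs and called them higher (adjusted p = 0.0319, 0.075 with a preset correlation of 0.05 and 0.146 with 0.1). A rank-based test of those 8 gave an adjusted p of 0.672 in the lower direction. Across 19210 genes the mezigdomide Wald statistic declined with GC content (Spearman rho = -0.227) and was higher in longer transcripts (rho = 0.186). In genes with a mean of at least 100 normalised counts these values were -0.277 and 0.342. In all, 24.2% of the fifth richest in GC were called lower, against 5.49% of the fifth poorest in GC.

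**Figure D3:**
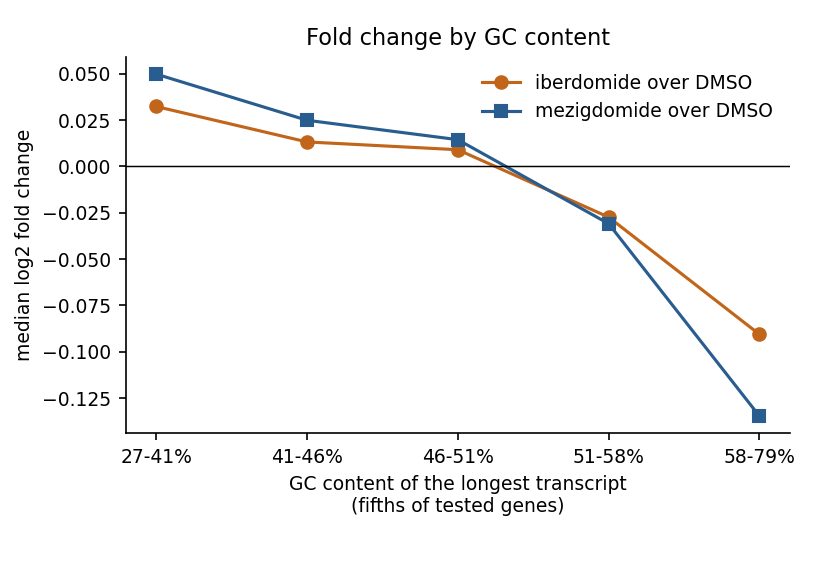
Median log2 fold change over DMSO of tested genes in 5 equal groups by GC content of the longest transcript (horizontal axis), for iberdomide (circles) and mezigdomide (squares), computed from the authors' deposited table of each drug. The medians of the group richest in GC are -0.091 and -0.13. Points carry no error bar, since genes are not independent replicates.

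The third comparison set the drugs against each other, at doses that differ (1 µM of iberdomide and 50 nM of mezigdomide), so that drug and dose are compared together. ABCA1 was 6.52-fold higher under iberdomide than under mezigdomide, a difference in log2 fold change (mezigdomide minus iberdomide) of -2.71 with a 95% interval from -3.21 to -2.21. SREBF1, which encodes the lipogenic regulator SREBP-1 (chromosome 17, 17810399 to 17837002), and MYLIP, which encodes a ubiquitin ligase for the LDL receptor (chromosome 6, 16129125 to 16148248), were called in opposite directions under the drugs. SREBF1 stood at 0.56 (SE 0.058) under iberdomide and -0.44 (SE 0.059) under mezigdomide, and MYLIP at 0.36 (SE 0.078) and -0.34 (SE 0.079), in the authors' deposited table. Conversely, the macrophage receptor VSIG4 was 2.39-fold higher under mezigdomide (difference 1.26, interval 0.73 to 1.79), as were HLA-DRA at 1.62-fold and CD36 at 1.5-fold.

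In total 21 of 19497 genes differed between the drugs, 9 higher and 12 lower under mezigdomide, in a two-sided normal test of the difference with Benjamini-Hochberg adjustment that took the errors of both fold changes as independent. That choice overstates the SE, because the drugs share their DMSO libraries. With an error correlation of 0.5 the count was 118, with 75 higher and 43 lower. Other genes lower under mezigdomide included the palmitoyltransferase ZDHHC8 (-1.60, adjusted p = 4.88e-14), OAF (-0.75, adjusted p = 0.000109), the retinoic acid receptor RARA (-0.66, adjusted p = 0.0316), GHDC (-0.64, adjusted p = 0.000222), BCR (-0.62, adjusted p = 0.0192) and EPX (-0.58, adjusted p = 0.00989). RARA lost its call with no filter on low counts, where its difference is the same (adjusted p = 0.0573), and after removal of the GC and length trend, where it was -0.60 (adjusted p = 0.104). RIPOR2 (1.07, adjusted p = 0.00766), the pore-forming macrophage protein MPEG1 (0.98, adjusted p = 0.0028), IL7R (0.65, adjusted p = 0.000503) and IQGAP2 (0.62, adjusted p = 0.00115) were higher under mezigdomide. IKZF1 differed by 0.21, with an interval from -0.077 to 0.51, and did not pass. Across 19210 genes the difference statistic declined with GC content (Spearman rho = -0.183) and was higher in longer transcripts (rho = 0.206). In genes with a mean of at least 100 normalised counts these values were -0.268 and 0.402.

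**Figure D4:**
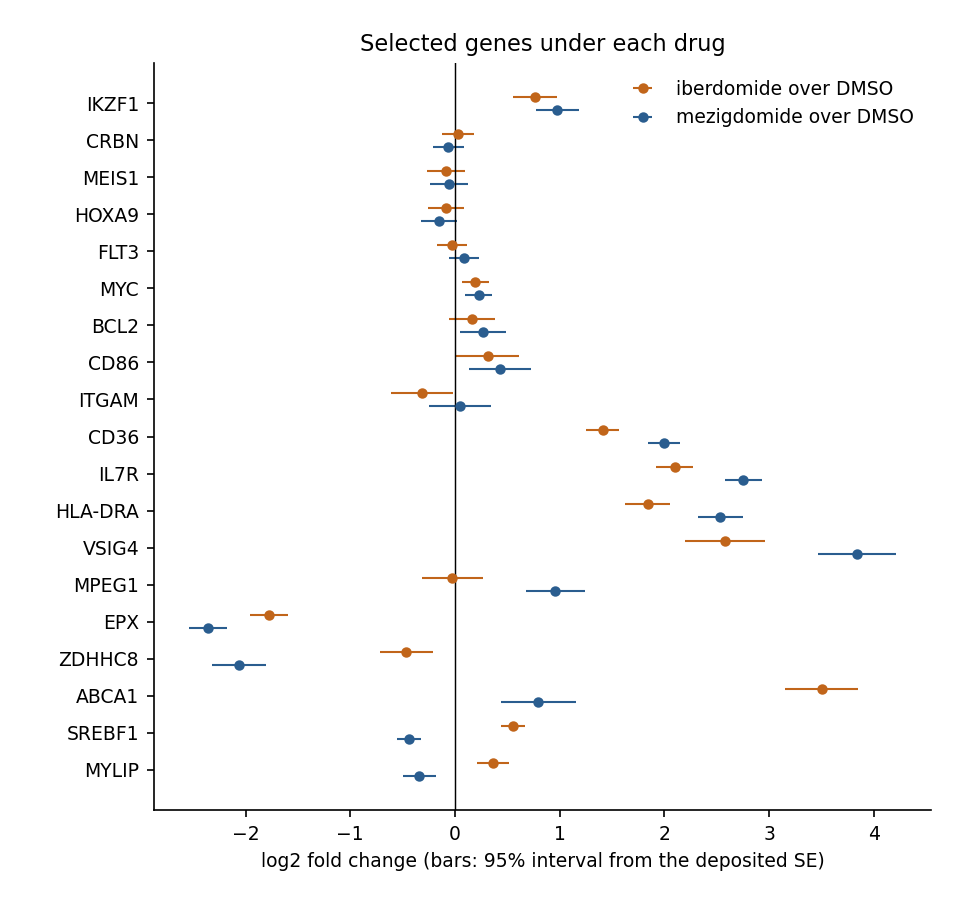
Log2 fold change over DMSO (horizontal axis) of 19 selected genes under iberdomide (orange) and mezigdomide (blue), from the authors' deposited table of each drug. Bars are 95% intervals from the deposited SE. ABCA1 lies at 3.50 under iberdomide and 0.80 under mezigdomide, and SREBF1 and MYLIP lie on opposite sides of 0.

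At the level of gene groups, cholesterol synthesis genes were higher under mezigdomide than under iberdomide, with a median difference of 0.19 over 23 members (camera adjusted p = 6.33e-16). In the normal test of single genes 0 passed over all genes, 6 were higher adjusted over the list alone, and 8 were higher and 0 lower at an unadjusted p under 0.05. SC5D differed by 0.38 (interval 0.16 to 0.60). MHC class II genes were also higher under mezigdomide (median difference 0.31, camera adjusted p = 8.18e-15), with 1 of 13 members, HLA-DRA, higher and 0 lower, or 4 and 0 adjusted over the list alone. Monocyte and macrophage genes had a median difference of 0.12 (camera adjusted p = 1.03e-09), with 1 of 24, CD36, higher and 0 lower, or 3 and 0 adjusted over the list alone. S phase genes had a median difference of -0.13 (camera adjusted p = 3e-16) and p53 targets of 0.095 (camera adjusted p = 8.39e-06), with 0 of 28 and 0 of 24 members past the normal test of single genes, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 2 S phase genes were lower and 3 p53 targets higher in that test. For 6 further lists the adjusted p passed at a preset correlation of 0.01 and not at 0.1. These were granule and neutrophil genes (median difference 0.12, adjusted p = 0.0319, then 0.199), interferon response (0.12, adjusted p = 0.0028, then 0.157) and MYC and ribosome biogenesis (-0.056, adjusted p = 0.0448, then 0.308). G2 and mitosis (-0.067, adjusted p = 0.0119, then 0.203), integrated stress response (-0.051, adjusted p = 0.0319, then 0.285) and AP-1 and NF-kB genes (-0.13, adjusted p = 0.00137, then 0.103) were the others. Of these 6, 5 were already lost at a preset correlation of 0.05, where AP-1 and NF-kB genes kept their call (adjusted p = 0.0255). With a mean of at least 50 the calls of granule genes (adjusted p = 0.0847), MYC (0.0966) and integrated stress response (0.0847) were lost. With the GC and length trend removed those of MYC (0.0756) and integrated stress response (0.06) were lost. In a rank-based test that of granule genes was lost (0.0707). The 8 remaining lists did not pass, with camera adjusted p of 0.606 for cereblon ligase and substrates, 0.836 for KMT2A and menin targets, 0.323 for stem and progenitor genes, 0.497 for MHC class I, 0.402 for surface antigens, 0.823 for the BCL2 family, 0.412 for erythroid and megakaryocyte markers and 0.297 for lymphoid markers. The lymphoid markers were called higher under mezigdomide with a mean of at least 50 (adjusted p = 0.00041). Of their 8 measured members only 1, IL7R, was called higher, and the median difference was -0.058.

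The genes called under both drugs were compared by direction. By the authors' deposited table, 1342 genes were higher and 1205 lower under both, 2547 in all, and 2, SREBF1 and MYLIP, had opposite calls. Independent lists of these sizes would share 158 and 150 genes in the same directions. Simulated unchanged groups against shared controls shared 0, but hardly any gene is called where nothing changes, so this value does not measure what shared controls add among called genes. Among the 2547 genes, 2021 (79.3%) had the larger change under mezigdomide, with a median absolute log2 fold change of 0.63 against 0.54. Across genes, which are not independent replicates, the fold changes under the drugs correlated at Pearson r = 0.934 and Spearman rho = 0.86, against 0.5 and 0.47 in simulations with no effect. The covariance was 0.144 against a simulated 0.0135, a difference of 0.131. The simulations gave both drugs the same DMSO error at the size of the deposited SE, so that share is already taken off in this difference. The 3 DMSO libraries cannot be divided into groups of at least 2. Whether the shared controls add more than the SE implies was therefore not measured.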

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

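The list of liver X receptor targets, the test of a stress response to GSPT1 loss and the removal of the GC and length trend were chosen after the report's results were seen. SREBF1 and MYLIP were called in opposite directions under the drugs, with differences (mezigdomide minus iberdomide, log2) of -0.999 and -0.699. Other genes that differed between the drugs are in the report. Lists that differed between the drugs in the camera test were flagged too, given here as median differences in log2 fold change. They were 0.122 for monocyte and macrophage maturation, 0.119 for granule and neutrophil genes, 0.116 for interferon response, 0.306 for MHC class II, 0.0951 for p53 targets and 0.187 for cholesterol synthesis. The medians were -0.0562 for MYC and ribosome biogenesis, -0.128 for S phase, -0.067 for G2 and mitosis, -0.0508 for integrated stress response and -0.127 for AP-1 and NF-kB genes. Rows that name no gene held a summed mean of 7.96 normalised counts, more than 3 per library.

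ABCA1, SREBF1 and MYLIP, all known targets of the liver X receptors, the nuclear receptors that sense oxysterols, were higher under iberdomide than under mezigdomide. A list of other such targets, written before their values were seen, was lower under mezigdomide (camera p = 0.00197, adjusted p = 0.119 with a preset correlation of 0.1), with 0 of 15 members past the test by themselves, so a wider difference in these targets may be present. Removal of a GC content and length trend between the drugs, fitted over all tested genes, moved their differences little. This argues against the trend as fitted being their whole cause. The trend was stronger in genes with a mean of at least 100 normalised counts, from which the fit may remove too little. ABCA1 went from -2.71 to -2.79, SREBF1 from -0.999 to -0.963 and MYLIP from -0.699 to -0.699. The calls of 3 of the 3 genes were kept, but these genes were picked for large differences that could hardly lose them. Members such as NR1H3 (2.02 and 1.92), PLTP (1.81 and 1.66) and SMPDL3A (0.86 and 0.82) rose under both drugs in the authors' deposited table, so the receptor targets did not all separate the drugs. The doses differ, and whether drug or dose sets the difference stays open as untested.

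Many of the largest falls under mezigdomide were in GC-rich genes, with a median GC content of 62.2% for the 10 largest against 48.2% for all tested genes. A GC content and length trend across all genes was present (Spearman rho = -0.227 between GC content and the Wald statistic, and 0.186 between transcript length and that statistic), which may add to these falls. It was stronger in genes with a mean of at least 100 normalised counts (rho = -0.277 and 0.342), from which the largest falls were taken. Removal of the trend as fitted over all tested genes took away little of these falls, with LRFN3 moving from -3.46 to -3.29 and IGLL1 from -4.10 to -3.92. This argues against the trend as fitted being their whole cause. The fit may remove too little from the genes in which the trend is stronger. The calls of 10 of the 10 genes were kept, but falls this large could hardly lose them, so that count adds nothing. Without values per library, a library preparation effect and a biological effect on GC-rich or short genes remain open as sources of the trend.

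Integrated stress response genes were lower under both drugs. Removal of the GC content and length trend, fitted over all tested genes, left the list called lower under mezigdomide (camera adjusted p = 1.16e-10). This argues against the trend as fitted being the whole cause there. The fit may remove too little from genes with higher counts, where the trend was stronger. A stress response from loss of GSPT1 protein would make these genes higher under mezigdomide. Of 26 members 0 were higher and 19 lower, with a median of -0.443 (camera adjusted p = 2.38e-11, 0.000186 with a preset correlation of 0.1). These values argue against a net rise of the list at 72 h, although they had been seen before the explanation was written down. An earlier response was not tested. GSPT1 protein was not measured. No further biological explanation was tested, and the drugs and their doses stay open as sources.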

How the results depend on the processing

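No paired analysis was possible because the tables hold no values per library, and for the same reason leaving out each replicate, the other normalizations and tests, the fit of 6 libraries, the estimated correlation, the self-contained list test, the pseudocounts and other splits of the libraries were not run. All alternatives named here except the filters and the fold threshold were chosen after seeing the data. An absolute log2 fold change of at least 1 left 453 genes under iberdomide, 649 under mezigdomide and 7 between the drugs, by its construction, and an error correlation of 0.5 raised the last count from 21 to 118, since it lowers the standard error. With no filter, a mean of at least 50, centring, the GC and length trend removed or protein-coding genes only, the counts ran from 2410 to 2752, from 3788 to 4437 and from 19 to 24, within 1.5 times the main counts. Of 57 list tests, 11 lost their call at a preset correlation of 0.05, 16 at 0.1, 3 with the GC and length trend removed, 4 with a mean of at least 50 and 7 in the rank-based test. With a mean of at least 50, 1 was newly called, lymphoid markers between the drugs (adjusted p = 0.00041). In the rank-based test 2 were newly called, and among the 7 lost the lymphoid list turned to lower under iberdomide (adjusted p = 0.853) and mezigdomide (adjusted p = 0.672). IL7R was the only lymphoid member called higher under either drug (2.10, SE 0.090, and 2.75, SE 0.089). The list medians were -0.0074 and -0.15, so the camera calls do not show a rise of most members. The list test was not repeated without IL7R. Of 299 gene results, 9 lost and 2 gained a call with the GC and length trend removed and 3 lost it with no filter. After centring 2 lost and 1 gained it, and 2 gained it with protein-coding genes only. The other 2 alternatives covered fewer results. With a mean of at least 50, 2 gained a call and 273 stayed the same. An error correlation of 0.5, which concerns only the difference between the drugs, gave 12 gains with 85 the same. No direction of a called gene turned in any of these. At this depth, genes under a mean of 2.87 (iberdomide) or 2.01 (mezigdomide) normalised counts have no adjusted p. Of the lymphoid and erythroid markers 8 and 10 were tested under iberdomide, and whether depth or lack of expression sets these numbers was not tested.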

Other observations

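The lists in this part were chosen after seeing the data. Their camera tests took the members tested under both drugs, which were 13 tissue macrophage, 9 eosinophil and 15 liver X receptor genes. Genes of tissue macrophages beyond the fixed lists had 5 of 13 measured members higher and 1 lower under iberdomide, and 6 of 14 higher and 1 lower under mezigdomide, by the authors' deposited table (camera adjusted p = 2.05e-07 for both). The coagulation factor subunit F13A1 rose 7.93-fold under iberdomide and 10.6-fold under mezigdomide in the authors' deposited table. The scavenger receptor MARCO (1.23 and 1.61), the receptor kinase AXL (0.97 and 1.08), MS4A4A (0.95 and 1.09) and MS4A7 (0.72 and 0.76) rose under both drugs, while the chemokine CCL2 fell (-1.09 and -1.16), in the authors' deposited table. Eosinophil lineage genes had 3 of 9 measured members lower and 1 higher under iberdomide (camera adjusted p = 0.0339) and 4 of 10 lower and 1 higher under mezigdomide (camera adjusted p = 0.0269) by the authors' deposited table. The galectin gene CLC (-1.86 and -2.41), PRG3 (-1.07 and -1.53) and the interleukin-5 receptor IL5RA (-0.97 and -1.08) fell under both drugs in the authors' deposited table. Their means were low, at 61.3, 42.8 and 9.29 normalised counts. PRG2, at a mean of 19752.5, did not pass the Wald test under iberdomide (-0.26, adjusted p = 0.153) and fell under mezigdomide (-0.46, adjusted p = 0.00135) in the authors' deposited table. It shares 43.0% of its exon bases with another gene on the same strand. The eosinophil list was no longer called at a preset correlation of 0.05 (adjusted p = 0.0752 and 0.0674) or 0.1 (adjusted p = 0.138 and 0.125). Both calls were also lost in a rank-based test (adjusted p = 0.0973 and 0.17) and with a mean of at least 50 (adjusted p = 0.0837 and 0.0826).

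Cytosolic aminoacyl-tRNA synthetase genes had 5 of 18 members lower and 0 higher under iberdomide (camera adjusted p = 0.0385) and 7 lower and 0 higher under mezigdomide (camera adjusted p = 0.0236) by the authors' deposited table. Both calls were lost at a preset correlation of 0.05 (adjusted p = 0.112 and 0.0752) or 0.1 (0.204 and 0.165) and with a mean of at least 50 (0.0826 and 0.0649). With the GC and length trend removed the iberdomide call was lost (adjusted p = 0.0521). FARSA (-0.39 and -0.55), MARS1 (-0.32 and -0.38) and GARS1 (-0.25 and -0.30) were among those that fell under both drugs in the authors' deposited table. Cytosolic ribosomal protein genes did not pass against DMSO (camera adjusted p = 0.412 and 0.322, the former 0.0312 in the higher direction in a rank-based test), with 1 and 2 of 84 members lower and 0 higher by the authors' deposited table. Between the drugs they were lower under mezigdomide, with a median difference of -0.093 (camera adjusted p = 6.11e-07, 0.0813 with a preset correlation of 0.1). The 13 mitochondrially encoded protein genes did not pass against DMSO (camera adjusted p = 0.412 and 0.194, the latter 0.0312 in the lower direction in a rank-based test), and between the drugs had a median difference of -0.069 (adjusted p = 0.0498), a call lost at a preset correlation of 0.05 (adjusted p = 0.112) or 0.1 (adjusted p = 0.204), with a mean of at least 50 (adjusted p = 0.1) and with the GC and length trend removed (adjusted p = 0.0657). Liver X receptor targets beyond those named in the report had 5 of 15 members higher and 0 lower under iberdomide (camera adjusted p = 1.65e-05) and 6 of 17 higher and 2 lower under mezigdomide (camera adjusted p = 0.0128, 0.125 with a preset correlation of 0.1, 0.0606 with a mean of at least 50 and 0.237 in a rank-based test) by the authors' deposited table. Apolipoprotein E stood at 1.25 and 0.69 under the drugs in the authors' deposited table.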
